A study of Mus musculus with 9 samples.

How the data were processed

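Total RNA from sorted mouse cells was measured on 9 Agilent arrays with 1 colour channel, 3 arrays in each of 3 groups. The groups were control embryonic stem (ES) cells, Max knockdown ES cells and primordial germ cells (PGCs) from E13.5 embryos, and each array was assigned through its deposited title. Labelling started from 100 ng of RNA, with Agilent's 1-colour spike-in transcripts added, per the labels' protocols. The study's design text states that the replicates of a group were biological, and what a replicate number marks is not given in the sources used here.

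The scanner files hold the intensity of each spot in Cy3, extracted with Agilent Feature Extraction 10.7.3.1, per the file headers. In the column used here, the authors' extraction had already subtracted the local background from the intensity and detrended it, per the file headers. Each array carried 43020 spots of 39429 probes besides controls, and 399 of the probes had 10 spots each. The deposited value table of the same arrays holds log2 values whose scale and centring are not stated. Compared with the scanner values, its columns ran in the same direction and matched log2 signals scaled on the 75th percentile and centred on each probe's median, with r across probes from 0.99983 to 0.99997 per array. The medians of its columns were -0.02, -0.12, -0.07, 0, 0, 0, 0, 0.34 and 0.39 in the order of the arrays. Whether further steps were applied to it stays unknown.

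For the main values, spots of a probe were averaged, log2 was taken of the processed signal, and the array's 75th percentile was subtracted. Control spots were left out, as were 65 probes with an outlier flag on an array, and no spot was saturated. Of the 39364 probes used, 26006 were named by matching the RefSeq accession of the array file to a gene table of assembly GRCm38.p6, used for names only because the array header gives mm9. The other 13358 probes kept the name in the file. Probes that shared a gene or identifier were reduced to the one with the highest mean over all arrays, which left 32450 genes or identifiers. A gene was tested if it was well above background on all arrays of at least 1 group, which left 20443, of which 14440 had a matched symbol.

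A single fit of the 3 groups was made over all 9 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over genes within a comparison and an adjusted p threshold of 0.05. Genes changed at least 2-fold are given beside that count. Errors of log2 differences are standard errors (SE) of this fit. With 3 arrays against 3, an exact permutation test of a single gene cannot go below 0.1, so the calls rest on the spread shared across genes. Where a gene was not well above background on any array of a group, the ratio is given as a lower bound ("at least N-fold"), taken against the lowest signal of a probe well above background on each array of that group or the dim probe's own signal if that was higher. Folds without these words are fitted values.

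The gene lists, 25 in number, were written before the data were examined, together with the tests, the alternatives and the rule for named genes. A list was tested against all other genes with camera of limma, with a preset inter-gene correlation of 0.01 and again with an estimated one, and Benjamini-Hochberg adjustment over the lists of a comparison. Some genes stand in several lists: the germ cell genes share 15 members with the PRC1.6 targets and 2 with the meiosis genes, and the meiosis genes share 12 with the PRC1.6 targets. Named were Max, Ddx4 and Pou5f1 in every comparison. Also named were the 6 largest rises and the 6 largest falls of each comparison among symbols past the test and 2-fold, with no overlap of the arrays and a bright group above background on all 3 arrays. From each list, the members with the strongest test were named (2, or 4 for germ cell genes, meiosis genes and naive pluripotency), with the strongest member against the list's median. Some genes that the rule names are left out of the text, such as those whose probes disagreed. For genes with several probes, the other probes of each named gene were compared, and where they differed by over 1.5-fold from the probe used in a comparison described, their values are given once.

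The slide, read from the headers, was treated as a batch. Slide 1 held control 1, control 2, Max knockdown 1 and Max knockdown 2, slide 2 held control 3 and Max knockdown 4, and the PGCs lay on slides 3 and 4. For knockdown against control, slide was fitted as a block and each slide was also taken alone. For PGCs, it was fitted as a random block.

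Alternatives were quantile normalization, scaling on the spike-in probes (7 of 10 used), no filter on dim genes, a filter on all 9 arrays, the mean of a gene's probes, every probe by itself, an intensity trend in eBayes, fits of only the groups compared, the deposited table, replicate and slide blocks, and leaving out each array. The planned normexp correction needs a mean signal column, which the scanner files used here lack, so normexp (offset 50) was run on the median signal and its background. That fit was disturbed by spots whose background lay above their signal, 11 on the first and 3 on the second Max knockdown array, and was repeated without them. Values given for normexp on median signals are from the first, disturbed fit. No named gene or list that passed in the main fit turned its sign in the repeat. Both versions were chosen after seeing the data.

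The steps were tested on simulated data with the real design. For Max knockdown against control, over 20443 genes, 80.6% of 67 genes changed by 1 on the log2 scale and 13.4% of 67 changed by 0.5 were recovered, with 3.73% false calls. The PGC comparison with control recovered 74.6% and 8.96% of such genes with 5.51% false calls, and the PGC comparison with knockdown cells 74.6% and 16.4% with 3.20% false calls. No list was called when none was shifted, but the simulated genes varied independently. This check therefore cannot show what correlation between genes does to the list test. In the real data the estimated correlation was 0.17 for germ cell genes and 0.43 for 2-cell-like genes. The overlap of both comparisons against control was set beside 100 simulations of unchanged groups against those controls. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.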

Results

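Transcript levels were measured in 3 groups of sorted mouse cells, each on 3 arrays. VV3 is a male ES cell line of 129SV background that carries Venus, a yellow fluorescent protein, under the promoter of Ddx4 (Vasa), a germ cell RNA helicase gene. Control cells had received a non-silencing siRNA and were sorted as live single cells 3 days later. Max knockdown cells had received siRNA against Max, which encodes a protein that pairs with MYC and with MGA. Only Venus-positive cells were collected, so siRNA and Venus gate differed together. PGCs, the embryonic precursors of sperm and eggs, were GFP-positive cells from the genital ridges of male E13.5 embryos of MCH x C57BL6/J background. On each array, between 58.2% and 67.6% of the 43020 spots were well above background, and no spot was saturated. Across genes, replicates correlated at 0.991 to 0.995, control with knockdown arrays at 0.966 to 0.974, and ES cell with PGC arrays at 0.866 to 0.882. No 2 arrays held an identical value for any gene.

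The targeted gene was low in every knockdown array. On the log2 scale relative to the 75th percentile of an array, Max stood at 2.75, 2.64 and 2.76 in control cells, at 0.49, 0.76 and 1.02 in Max knockdown cells, and at 3.67, 3.56 and 3.47 in PGCs. Max fell 3.89-fold in knockdown cells (log2 -1.96, SE 0.13, limma adjusted p = 2.7e-05), by 2.07 within slide 1 (log2 -2.07) and by 1.74 within slide 2 (log2 -1.74). Ddx4 rose 6.22-fold (log2 2.64, SE 0.13, adjusted p = 7.1e-06), a value that is not independent of the sort because the Venus gate reads the promoter of this gene. Pou5f1, which encodes the pluripotency factor Oct4, did not differ beyond the spread between replicates (log2 0.04, SE 0.12, adjusted p = 0.82).

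**Figure D1:**
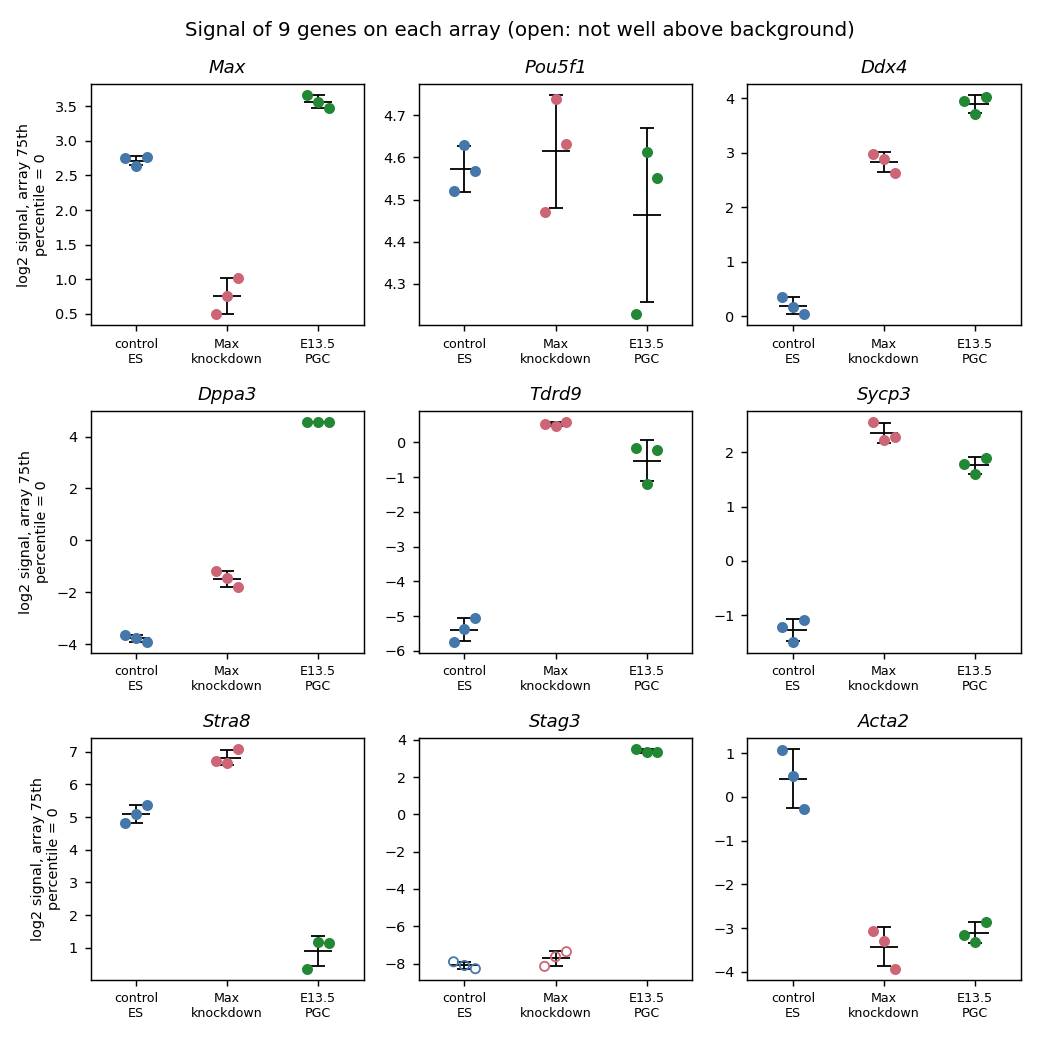
Log2 signal relative to the 75th percentile of each array for 9 genes, 1 point per array, with the mean and SD of each group of 3 arrays; open symbols mark a group not well above background. The knockdown arrays lie lowest for Max, at 0.49 to 1.02, and above the control arrays for Ddx4, Tdrd9 and Sycp3, while Stag3 is bright in PGCs alone among the 3 groups.

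The first comparison asks how Venus-positive Max knockdown cells differ from control ES cells. In the knockdown cells 40 of 54 germ cell genes, 35 of 48 meiosis genes and 20 of 22 genes of the 2-cell-like state rose. As lists, the meiosis genes passed with either correlation (adjusted p = 0.048 with an estimated correlation), and germ cell and 2-cell-like genes only with the fixed one (adjusted p = 0.0938 and adjusted p = 0.21 with an estimated correlation). Of fibroblast, primitive endoderm and glycolysis genes, 8 of 15, 11 of 20 and 13 of 23 fell, and these lists too passed only with the fixed one (adjusted p = 0.19, 0.47 and 0.21 with an estimated correlation). Of 20443 genes tested, 3738 rose and 4466 fell, and 1295 of the rises and 987 of the falls were at least 2-fold. Rises made up 45.6% of the 8204 changes, against 70.6% of 1010 with spike-in scaling and 65.1% of 887 with normexp on median signals. Without the spots that disturbed that normexp fit, they made up 49.8% of 6816. At 2-fold, rises made up 56.8% of 2282, against 70.6% of 1010 with spike-in scaling. With normexp they made up 69.6% of 718, and 62.4% of 1042 without those spots. The 75th percentile over the spike-ins followed the slide within both ES cell groups. No slide block was fitted with spike-in scaling, so that difference widened the spread of every gene there.

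Nxf2, an mRNA export factor of the male germline, rose 85.3-fold (log2 6.42, SE 0.37, adjusted p = 1.2e-05). Tdrd9, a helicase of the piRNA pathway that silences transposons, rose 60.2-fold (log2 5.91, SE 0.28, adjusted p = 5.1e-06), with 2 of 3 control arrays above background. Ctcfl, the testis paralog of the chromatin factor CTCF, rose 59.8-fold (log2 5.90, SE 0.33, adjusted p = 1.2e-05). Asz1, a germ granule protein of the piRNA pathway, was at least 11.2-fold higher (adjusted p = 3.9e-06). Mlc1, a membrane protein known from astrocytes, rose by 5.21 and Sycp1-ps1 by 5.11 on the log2 scale (adjusted p = 7.9e-07 for both), each above background on 2 of 3 control arrays. Sycp1-ps1 is a pseudogene, and its probe may share sequence with Sycp1, so the source of its signal is uncertain.

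Acta2, smooth muscle actin, fell by 3.84 (log2 -3.84, SE 0.35, adjusted p = 9.7e-05), and Actc1, cardiac actin, fell by 3.96 (log2 -3.96, SE 0.55, adjusted p = 0.00075). Megf10, an engulfment receptor, fell by 4.23 (log2 -4.23, SE 0.40, adjusted p = 0.00012). Fgfbp3, which binds fibroblast growth factors, had a log2 change of -3.97 (adjusted p = 0.00018). Of the 3 knockdown arrays, 1 measured Actc1, 1 measured Megf10 and 2 measured Fgfbp3 above background. Rflna, a filamin-binding protein, was at least 9.75-fold lower (adjusted p = 1.7e-05). Ankrd1, an ankyrin-repeat protein of muscle, was at least 3.64-fold lower (adjusted p = 4.1e-05), but stood at 0.12 with normexp on median signals, where the other 5 also missed the threshold. The sign of Ankrd1 did not turn when that fit was repeated without the disturbing spots.

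Of 54 germ cell genes measured, 40 rose, 3 fell and 11 did not pass the test (42 rises and 3 falls adjusted over the list alone). Their median log2 change was 1.65, or 1.48 with dim genes at their bound (camera adjusted p = 1.6e-19). The call was lost under the other correlation (adjusted p = 0.0938 with an estimated correlation). Mov10l1, a piRNA helicase, rose 20.9-fold (log2 4.39, SE 0.13), Slc25a31, an ADP/ATP carrier of sperm, by 4.26 on the log2 scale (SE 0.15), Fkbp6, a co-chaperone of the piRNA pathway, 14.2-fold (log2 3.83, SE 0.11) and Hormad1, a meiotic chromosome axis protein, 7.13-fold (log2 2.83, SE 0.12). Zbtb16, a factor of spermatogonial stem cells, fell by 1.86 (log2 -1.86, adjusted p = 0.00071), a sign that turned with normexp on median signals (0.06) but not in the repeat of that fit. Beside these, 3 of 24 markers of gonadal somatic cells rose and 3 fell, with a median of -0.07 (camera adjusted p = 0.89), a mean of 0.01 and a test direction upward, or -0.02 with dim genes at their bound and 0.67 with normexp on median signals. Among those, Sox9, the Sertoli cell factor, was at least 2.23-fold lower, but stood at 0.63 with normexp on median signals. The sign of Sox9 did not turn in the repeat of that fit.

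Meiosis genes rose in 35 of 48 cases, with 2 falls and 11 that did not pass (35 and 3 adjusted over the list alone). Their median was 1.28, or 1.24 with bounds (camera adjusted p = 1.4e-14, and adjusted p = 0.048 with an estimated correlation). Sycp3, an axial element of the synaptonemal complex, rose 12.3-fold (log2 3.62, SE 0.14, adjusted p = 1.8e-06). Tex11, an X-linked crossover factor, rose 7.51-fold (log2 2.91, SE 0.10, or 1.98 by another probe), and Syce1, a central element protein of the same complex, 7.44-fold (log2 2.89, SE 0.10). Stra8, which starts meiosis in response to retinoic acid, was bright in control cells, with a mean of 5.09, and rose by a further 1.73. Cntd1, a crossover regulator, was at least 2.13-fold lower, but stood at 0.83 with normexp on median signals. The sign of Cntd1 did not turn in the repeat of that fit. Germline targets of PRC1.6, the Polycomb complex that holds MGA and MAX, rose in 23 of 25 cases with no fall (23 and 0 adjusted over the list alone). Their median of 2.64 was the same with bounds (camera adjusted p = 8.4e-20, and adjusted p = 0.048 with an estimated correlation). This list held Mov10l1 and Syce1 and shares 15 members with the germ cell genes.

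Not every germ cell group moved. Early PGC specification genes counted 2 rises and 4 falls of 20 (2 and 3 adjusted over the list alone; camera adjusted p = 0.93), with a median of -0.16, a mean of -0.04, a test direction upward and a median of 0.29 with normexp on median signals. Dppa3 (Stella), a maternal and PGC protein, rose 4.89-fold (log2 2.29, SE 0.15, adjusted p = 2.0e-05), and the adhesion receptor gene Pecam1 rose by 0.83 (adjusted p = 0.00014). Male E13.5 differentiation genes counted 5 rises and 7 falls of 20 (6 and 7 adjusted over the list alone; camera adjusted p = 0.99), with a median of 0.06, a mean of 0.41 and a test direction downward. Tdrd9 and Ctcfl led its rises.

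Genes of the 2-cell-like state, a rare state of ES cells that resembles 2-cell embryos, rose in 20 of 22 cases, with no fall (20 and 0 adjusted over the list alone). Their median was 2.62, or 2.53 with bounds (camera adjusted p = 1.3e-10, but adjusted p = 0.21 with an estimated correlation). Arg2, a mitochondrial arginase, rose 7.98-fold (log2 3.00, SE 0.24, adjusted p = 6.5e-05) and Gm5662 rose 6.78-fold (log2 2.76, SE 0.26, adjusted p = 0.00013). Zscan4c and Zscan4f, factors of telomere maintenance, rose by 2.54 and 2.38, but near-identical copies make their probes unspecific, as for the preferentially expressed antigen gene Pramel16 (2.34). For Sp110 the probe used gave -0.05 (adjusted p = 0.77), other probes gave 3.17 and 2.54, and the mean of its probes 1.89. On the 9-array filter, the median was 0.76 (camera adjusted p = 0.088). That filter also removes members that are dim in PGCs but bright in both ES cell groups, such as Zscan4f. Only 2 of the 22 had a bound in this comparison, against 16 in PGCs against control, so the lower median does not bear on the removed members.

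Naive pluripotency genes rose in 10 and fell in 3 of 31 cases (11 and 3 adjusted over the list alone). The median was 0.36 (camera adjusted p = 0.011, but adjusted p = 0.47 with an estimated correlation), and 0.00 with normexp on median signals. The pluripotency factors Klf4 and Klf5 rose by 0.92 and 0.78, and Dppa2 rose by 0.91, while Lin28b, a regulator of let-7 microRNAs, fell by 0.76 (log2 -0.76, adjusted p = 0.00032). Formative and primed epiblast genes counted 3 rises and 10 falls of 18 (3 and 10 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 0.098). Cdh2, N-cadherin, fell by 2.26 (log2 -2.26, adjusted p = 6.3e-06) and Pou3f1 by 1.30 (log2 -1.30), whereas the Wnt effector Lef1 rose by 1.46.

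Fibroblast genes fell in 8 and rose in 1 of 15 cases (9 and 1 adjusted over the list alone), with a median of -1.13 (camera adjusted p = 0.0062, but adjusted p = 0.19 with an estimated correlation). Besides Acta2, Col1a2, a fibrillar collagen, fell by 2.36 (log2 -2.36, SE 0.22, adjusted p = 0.00011), while Col6a1 rose by 1.52. Primitive endoderm genes fell in 11 of 20 cases with no rise (12 falls and 1 rise adjusted over the list alone), with a median of -0.83 (camera adjusted p = 0.0044, but adjusted p = 0.47 with an estimated correlation). Amn, an endocytic membrane protein, fell by 1.31 (log2 -1.31) and Col4a1, a basement membrane collagen, by 1.46 (log2 -1.46).

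Among other lineages no list shifted. Mesoderm genes counted 2 rises and 6 falls of 15 (2 and 6 adjusted over the list alone; median -0.10, or -0.07 with bounds and 0.80 with normexp on median signals; camera adjusted p = 0.52), with Tbx6 at -1.07 (-0.44 by another probe) and Cdx1 at 1.17. Trophectoderm genes counted 3 rises and 6 falls of 15, over the list alone too (median -0.27, or 0.21 with normexp on median signals, camera adjusted p = 0.61), with the keratins Krt19, Krt8 and Krt7 at -2.11, -1.31 and 0.98. Neuroectoderm genes counted 6 falls of 14, over the list alone too (camera adjusted p = 0.34), with a median of 0.02, or -0.02 with quantile normalization, a mean of -0.30 and a test direction downward, and Nes at -1.67. Markers of blood and endothelium counted 2 rises and 2 falls of 13 (2 and 1 adjusted over the list alone; median 0.25, or 0.01 with bounds; camera adjusted p = 0.30). The endothelial receptors Tie1 and Tek rose by 2.84 and 1.13 and Flt1 fell by 0.89 (log2 -0.89).

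MYC targets in ribosome biogenesis and growth fell in 20 and rose in 6 of 54 cases (22 and 6 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 0.016, but adjusted p = 0.51 with an estimated correlation). Srm, spermidine synthase, fell by 0.77 (log2 -0.77, adjusted p = 0.0011). Glycolysis genes fell in 13 and rose in 1 of 23 cases (14 and 1 adjusted over the list alone), with a median of -0.34 (camera adjusted p = 0.0044, but adjusted p = 0.21 with an estimated correlation). The muscle-type phosphofructokinase gene Pfkm fell by 0.82 (log2 -0.82) and the aldolase gene Aldoc by 1.01 (log2 -1.01), and the hexokinase gene Hk2 rose by 0.38. p53 response genes fell in 11 and rose in 1 of 23 cases (12 and 1 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 0.013, but adjusted p = 0.19 with an estimated correlation). Polk, a translesion polymerase, fell by 0.97 (log2 -0.97) and Bbc3 (Puma), a killer of the BCL2 family, by 1.21 (log2 -1.21), while Pmaip1 (Noxa) rose by 0.82, a call lost without control replicate 2 or 3 or knockdown replicate 1 (adjusted p up to 0.0631).

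Partners of MAX and members of the MGA complex went both ways, with 9 rises and 8 falls of 27, over the list alone too (median 0.03, camera adjusted p = 0.52), and Mxd4, a MAX-binding repressor, rose by 1.81. Myc itself rose by 1.33 (adjusted p = 0.00074). Imprinted genes counted 2 rises and 12 falls of 31 (2 and 13 adjusted over the list alone; median -0.43, or 0.03 with normexp on median signals, camera adjusted p = 0.098), with Sgce and Phlda2 at -1.22 and -2.33. Cell cycle genes counted 4 falls of 36 and none adjusted over the list alone (median -0.11, camera adjusted p = 0.27), and the licensing factor Cdt1 stood at -0.61. The 26 DNA and H3K9 methylation genes include the metal transporter gene Slc11a1, to which an old name in the list was matched, and which did not pass here. They counted 5 rises and 6 falls, over the list alone too (camera adjusted p = 0.99), with a median of 0.00, a mean of 0.01 and a test direction downward. Interferon response genes counted 3 rises and 5 falls of 19, over the list alone too (median -0.09, or 0.37 with normexp on median signals, camera adjusted p = 0.94). Immediate-early and dissociation stress genes counted 4 rises and 6 falls of 23 (4 and 8 adjusted over the list alone; median -0.04, or 0.04 with normexp on median signals, camera adjusted p = 0.99), with Egr2 at -2.03. Y-linked genes counted 2 rises of 6, over the list alone too (median 0.40, or 0.06 with bounds, camera adjusted p = 0.27).

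**Figure D2:**
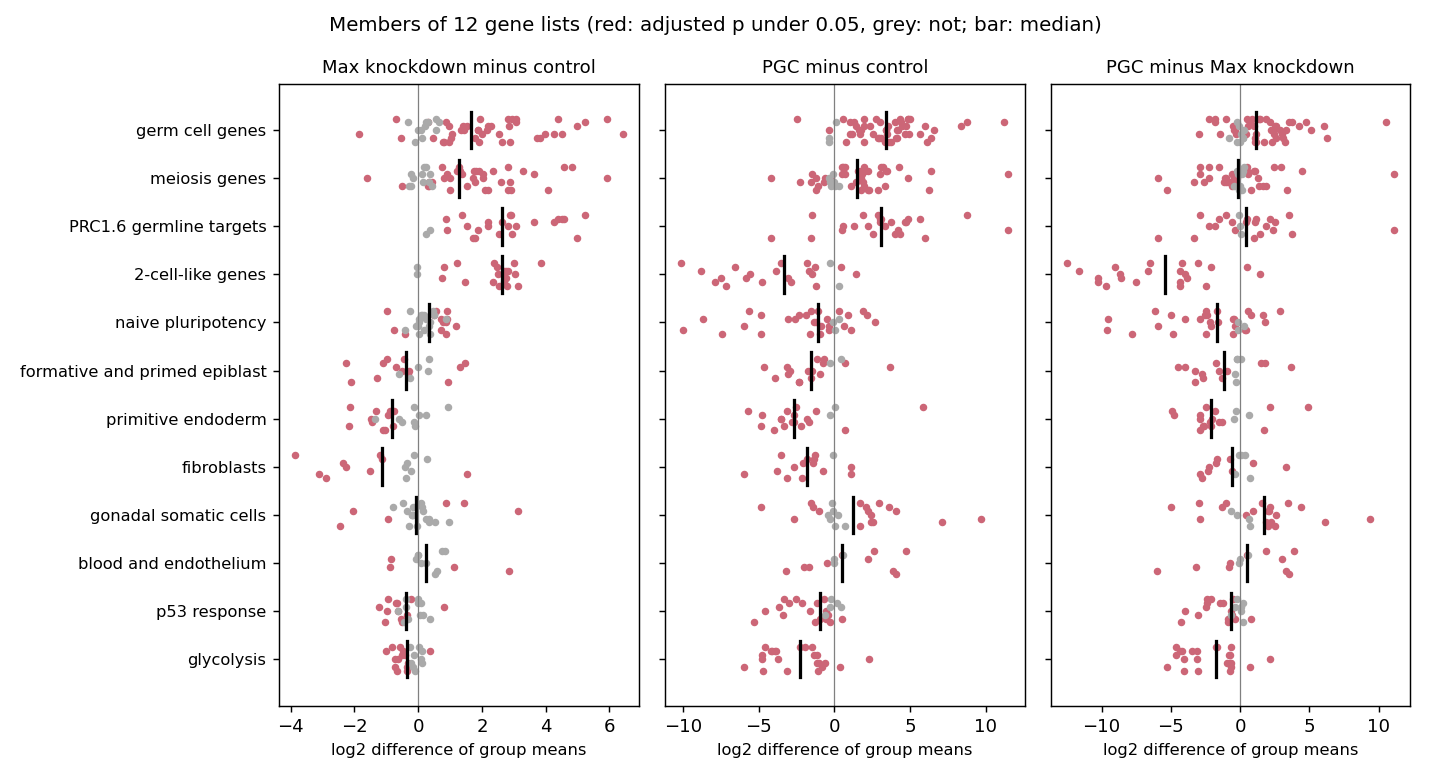
Log2 difference of each measured member of 12 gene lists in the 3 comparisons, in red where the adjusted p was under 0.05 and grey otherwise, with a bar at the median. In Max knockdown against control, the medians of the germ cell, meiosis, PRC1.6 and 2-cell-like lists lie at 1.65, 1.28, 2.64 and 2.62, and in PGCs against control the median of the 2-cell-like list lies at -3.30.

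Both slides that held control and knockdown arrays gave these shifts. Within slide 1 and slide 2, the median was 1.68 and 1.42 for germ cell genes, 1.32 and 1.32 for meiosis genes, 2.66 and 2.59 for PRC1.6 targets and 2.49 and 2.64 for 2-cell-like genes. It was 0.34 and 0.28 for naive pluripotency, -1.14 and -0.71 for fibroblasts, -0.76 and -0.96 for primitive endoderm, -0.27 and -0.18 for MYC targets, -0.40 and -0.46 for the p53 response and -0.28 and -0.41 for glycolysis. With slide as a block and the fixed correlation, these lists passed at adjusted p from 1.9e-16 for germ cell genes to 0.032 for MYC targets, and 9497 genes were called. Of the 10, all but the meiosis genes and PRC1.6 targets were lost over all arrays under the other correlation, from adjusted p = 0.0938 for germ cell genes to adjusted p = 0.51 for MYC targets with an estimated correlation. Spike-in scaling ended the calls of the naive pluripotency, MYC, p53 and glycolysis lists (adjusted p = 0.10, 0.22, 0.081 and 0.10), although their medians stayed at 0.35, -0.23, -0.38 and -0.34. That setting had no slide block, so the slide difference in the spike-ins widened the spread. Quantile normalization ended the calls of the MYC and glycolysis lists (0.18 and 0.087), and normexp on median signals those of naive pluripotency and the fibroblasts (median 0.00 and -0.10, adjusted p = 0.56 and 0.19). In the repeat without the spots that disturbed normexp, no list lost its call with the fixed correlation.

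The next comparison sets PGCs beside control ES cells. In PGCs 49 of 54 germ cell genes were higher (adjusted p = 0.17 with an estimated correlation), while 18 of 22 2-cell-like and 21 of 23 glycolysis genes were lower (adjusted p = 0.32 and adjusted p = 0.046 with an estimated correlation). Of 20443 genes, 8808 were higher and 6610 lower in PGCs, 4037 and 4141 of them at least 2-fold. Higher genes made up 57.1% of the 15418 changes, and 49.4% of the 8178 at 2-fold. With spike-in scaling they made up 13.2% of 8787, because the median of all genes moved from 0.18 to -0.79, so that directions in both PGC comparisons are relative to the 75th percentile. The 75th percentile over the spike-ins, relative to the mean of the 9 arrays, also followed the slide within control cells, at 0.74 and 0.73 on slide 1 and -0.50 on slide 2, so that shift cannot be told apart from a slide effect. Max was higher in PGCs (log2 0.85, SE 0.13, adjusted p = 0.00039), and -0.12 with spike-in scaling. Ddx4 was 13.1-fold higher (log2 3.71, SE 0.13, adjusted p = 6.7e-08), and Pou5f1 did not differ beyond the spread (log2 -0.11, SE 0.12, adjusted p = 0.43). Cell type, strain, origin and slide went together in this comparison, and a random slide block called 14760 genes.

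Stag3, the meiotic cohesin subunit, was at least 618-fold higher in PGCs (adjusted p = 4.2e-09). Nanos2, which commits germ cells to the male pathway, had a log2 difference of 11.21 (SE 1.01, adjusted p = 1.2e-05), with 1 of 3 control arrays above background. Without that array, control replicate 1, the fitted value was 12.17, but no control array was then above background. Its size is therefore not a measured ratio. Cst9, a cystatin of the developing testis, was at least 232.5-fold higher, Asb9, an adaptor of ubiquitin ligases, at least 155-fold, Asz1 at least 131-fold, and Bnc1, a zinc finger factor of germ cells and keratinocytes, at least 89.2-fold. At the other end, Bcl3, a regulator of NF-kB, was at least 343-fold lower, the peptide hormone gene Calca at least 248-fold by the probe used (another gave a log2 difference of -5.29), the water channel gene Aqp3 at least 240-fold and Zscan4f at least 224.0-fold. Fgf4, the growth factor that primes ES cells for differentiation, had a log2 difference of -10.00 (SE 0.24, adjusted p = 1.3e-08), with 1 of 3 PGC arrays above background.

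Of 54 germ cell genes, 49 were higher and 2 lower, over the list alone too, with a median of 3.41, or 3.20 with bounds (camera adjusted p = 4.5e-11, but adjusted p = 0.17 with an estimated correlation). Dppa3 was 325-fold higher (log2 8.34, SE 0.15), Tdrd5, a piRNA pathway protein, 84.0-fold (log2 6.39, SE 0.14), and Nanos3, a survival factor of PGCs, 22.6-fold (log2 4.50, SE 0.11). The tubulin gene Tuba3b was higher by 4.70 on the log2 scale (SE 0.12). Dmrtb1, a factor of spermatogonia, was at least 4.54-fold lower. PRC1.6 targets counted 22 higher and 3 lower of 25, over the list alone too, with a median of 3.05 also with bounds (camera adjusted p = 1.6e-05, but adjusted p = 0.17 with an estimated correlation). Stra8 was 18.3-fold lower (log2 -4.20, SE 0.24, adjusted p = 7.9e-07). Meiosis genes counted 31 higher and 10 lower of 48 (32 and 11 adjusted over the list alone), with a median of 1.47, or 1.23 with bounds (camera adjusted p = 0.0097, but adjusted p = 0.32 with an estimated correlation). Tex12, of the synaptonemal complex, was 18.9-fold higher (log2 4.24), and Dmc1, the meiotic recombinase, lower by 2.27 (log2 -2.27). This call ended on the 9-array filter (median 0.70, adjusted p = 0.12).

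Beside these, markers of gonadal somatic cells counted 12 higher and 5 lower of 24, over the list alone too (median 1.20 also with bounds, camera adjusted p = 0.24). Cst9 led them, while Nr0b1 (Dax1), also a pluripotency gene, stood at -4.85. Markers of blood and endothelium counted 6 higher and 4 lower of 13, over the list alone too (median 0.47, or -0.50 with spike-in scaling, camera adjusted p = 0.74). The alpha globin genes Hba-a2 and Hba-a1, near-identical copies, were higher by 4.06 and 3.89. Early PGC genes counted 12 higher and 5 lower of 20, over the list alone too (median 0.70, camera adjusted p = 0.13). With spike-in scaling their median was -0.26, where that of all genes was -0.79. Male E13.5 genes counted 10 higher and 8 lower of 20, over the list alone too (median 0.57, camera adjusted p = 0.69). Their median was -0.40 with spike-in scaling. Elavl2, a neuronal and germ cell RNA-binding protein, was higher by 3.42 and the Nodal co-receptor gene Tdgf1 stood at -5.98 (-8.35 and -7.72 by other probes).

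Naive pluripotency genes were lower in 21 and higher in 7 of 31 cases (21 and 8 adjusted over the list alone), with a median of -1.07 (camera adjusted p = 0.00063, but adjusted p = 0.32 with an estimated correlation). Besides Fgf4 and Tdgf1, the adhesion gene Jam2 stood at -5.64, while Dppa4 was higher by 2.13. Formative and primed epiblast genes were lower in 14 and higher in 2 of 18 cases, over the list alone too, with a median of -1.52, or -1.32 with bounds (camera adjusted p = 0.00025, and adjusted p = 0.046 with an estimated correlation). Tead2, a partner of YAP, stood at -4.65 and Dnmt3b, a de novo DNA methyltransferase, at -3.05. Sox4 stood at 0.67, and at -0.30 with spike-in scaling. The 2-cell-like genes were lower in 18 and higher in 2 of 22 cases, over the list alone too, with a median of -3.30, or -2.98 with 16 members at their bound (camera adjusted p = 2.5e-05, but adjusted p = 0.32 with an estimated correlation and 0.36 on the 9-array filter). Gm5662 was at least 79.6-fold lower, and Tbpl1, a TBP-like factor of spermatogenesis, was higher by 1.41.

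Primitive endoderm genes were lower in 16 and higher in 2 of 20 cases, over the list alone too (median -2.67, or -2.60 with bounds, camera adjusted p = 5.6e-05, but adjusted p = 0.32 with an estimated correlation). Lrp2 and Apoe, of endocytosis and lipid transport, stood at -5.70 and -4.76, and Afp, alpha-fetoprotein, was at least 18.6-fold higher. Fibroblast genes were lower in 12 and higher in 2 of 15 cases, over the list alone too (median -1.85, camera adjusted p = 0.0016, but adjusted p = 0.17 with an estimated correlation), led by Tagln, a smooth muscle actin-binding protein, at -5.97. Mesoderm genes counted 6 higher and 6 lower of 15, over the list alone too (camera adjusted p = 0.75), with a median of -0.05, a mean of 0.30 and a test direction downward. Lhx1 was higher by 4.07 and Wnt3 by 6.29, the latter with 1 of 3 control arrays above background. Trophectoderm genes counted 4 higher and 11 lower of 15, over the list alone too (median -1.67, or -1.30 with bounds, camera adjusted p = 0.051), with Krt19 at -4.28. Neuroectoderm genes counted 4 higher and 8 lower of 14, over the list alone too (median -0.49, camera adjusted p = 0.13), with Olig2 at least 23.1-fold lower and the Notch target Hes5 higher by 3.93.

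Glycolysis genes were lower in 21 and higher in 2 of 23 cases, over the list alone too, with a median of -2.29 (camera adjusted p = 1.3e-08, and adjusted p = 0.046 with an estimated correlation). The liver-type phosphofructokinase gene Pfkl was 26.9-fold lower (log2 -4.75, SE 0.11, adjusted p = 1.0e-08) and Hk2 14.4-fold (log2 -3.85, SE 0.09, adjusted p = 1.0e-08), while the lactate dehydrogenase gene Ldhb was 4.76-fold higher (log2 2.25, SE 0.09). p53 response genes were lower in 17 and higher in 1 of 23 cases, over the list alone too (median -0.94, camera adjusted p = 5.6e-05, and adjusted p = 0.046 with an estimated correlation), with Perp, an apoptosis effector, at -5.32 and Ccng1, cyclin G1, at -3.37. The single rise was Mdm2 (0.50), which stood at -0.46 with spike-in scaling. Cell cycle genes were lower in 24 and higher in 3 of 36 cases, over the list alone too (median -0.49, camera adjusted p = 0.00032, but adjusted p = 0.32 with an estimated correlation). Rrm2, of ribonucleotide reductase, stood at -2.60 and Ccnd1, cyclin D1, at -2.79. Ccnb2 stood at 0.35, and at -0.61 with spike-in scaling. MYC targets counted 34 higher and 12 lower of 54 (34 and 13 adjusted over the list alone; median 0.40, or -0.56 with spike-in scaling, camera adjusted p = 0.11), with Ldha, lactate dehydrogenase A, at -4.76 (-6.04 and -6.42 by other probes).

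Interferon response genes were lower in 14 and higher in 2 of 19 cases (14 and 3 adjusted over the list alone), with a median of -1.49, or -1.24 with bounds (camera adjusted p = 0.0032, but adjusted p = 0.48 with an estimated correlation). Oas2 stood at -3.95, and Ddx58 (RIG-I), a viral RNA sensor, was higher by 3.62 (1.85 by another probe). Immediate-early and stress genes were lower in 16 and higher in 6 of 23 cases, over the list alone too (median -1.92, camera adjusted p = 0.0053, but adjusted p = 0.40 with an estimated correlation), with Gadd45b at -2.65 and the heat shock gene Dnajb1 higher by 2.19. Imprinted genes were lower in 16 and higher in 6 of 31 cases (15 and 6 adjusted over the list alone; median -0.45, camera adjusted p = 0.013, but adjusted p = 0.32 with an estimated correlation), with Sgce at -4.49, Slc38a4 at -3.31 and Ndn higher by 1.55. MAX partners counted 11 higher and 6 lower of 27, over the list alone too (median 0.21, or -0.76 with spike-in scaling, camera adjusted p = 0.55), with Rybp, of the PRC1.6 complex, at -2.47. DNA and H3K9 methylation genes counted 12 higher, with Slc11a1 among them, and 10 lower of 26, over the list alone too (camera adjusted p = 0.69), with a median of 0.19, a mean of -0.52 and a test direction downward, and a median of -0.78 with spike-in scaling. The H3K9 demethylase gene Kdm4c stood at -3.07. Y-linked genes counted 3 higher and 1 lower of 6, over the list alone too (median 0.93, or -0.04 with spike-in scaling, camera adjusted p = 0.45), with Eif2s3y at 1.72 and Ddx3y at -1.23.

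Set directly against Max knockdown cells, PGCs had 35 germ cell genes higher and 10 lower of 54, with a median of 1.11, or 0.15 with spike-in scaling. Meiosis genes went both ways, and 20 of 22 2-cell-like genes were lower. The germ cell and 2-cell-like calls were lost under the other correlation (adjusted p = 0.51 and adjusted p = 0.50 with an estimated correlation). Of 20443 genes, 9145 were higher and 6439 lower in PGCs, 4156 and 4031 of them at least 2-fold. Higher genes made up 58.7% of 15584, against 12.1% of 8324 with spike-in scaling, where the median of all genes moved from 0.21 to -0.76, and 50.8% of 8187 at 2-fold. Max was 7.01-fold higher in PGCs (log2 2.81, SE 0.13, adjusted p = 2.9e-07). Ddx4 was 2.10-fold higher (log2 1.07, SE 0.13, adjusted p = 9.2e-05), but 0.11 and not past the test with spike-in scaling, and Pou5f1 did not differ beyond the spread (log2 -0.15, SE 0.12, adjusted p = 0.28). A random slide block called 14973 genes.

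Stag3 was at least 480-fold higher in PGCs than in knockdown cells (adjusted p = 5.5e-09), Cst9 at least 181-fold, the protease gene Prss29 at least 89.1-fold by the probe used (against control it gave 7.95 and another probe 5.24), Fam163a at least 78.8-fold and Wnt3 at least 70.4-fold. Nanos2 had a log2 difference of 10.54 (SE 1.01, adjusted p = 1.8e-05), with 1 of 3 knockdown arrays above background, and stood at 9.88 without knockdown replicate 1. Without the array above background, knockdown replicate 2, the fitted value was 11.64. No knockdown array was then above background, so its size is not a measured ratio. Among the falls, Zscan4f was at least 1162-fold lower, Zscan4c at least 587-fold, and Pramel16, Pramel39 and Pramel31 at least 265.0-fold, 223.5-fold and 188.5-fold, all genes with near-identical copies. Against control, the probes used gave -7.17 for Zscan4c, -7.40 for Pramel39 and -7.43 for Pramel31, and other probes -5.56 and -8.16, -6.71 and -6.57. Aqp3 was at least 352-fold lower.

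Germ cell genes counted 35 higher and 10 lower of 54, over the list alone too, with a median of 1.11 also with bounds (camera adjusted p = 0.0052, but adjusted p = 0.51 with an estimated correlation), and a median of 0.15 with spike-in scaling. Tdrd5 was 76.4-fold higher (log2 6.26, SE 0.14), Dppa3 66.5-fold (log2 6.05, SE 0.15) and Nanos3 19.4-fold (log2 4.28, SE 0.11). Elavl2 was higher by 3.32 on the log2 scale, while Hormad1 stood at -2.25 (against control 0.59, and -0.17 by another probe). Meiosis genes counted 15 higher and 21 lower of 48, over the list alone too (median -0.13, camera adjusted p = 0.25). Meioc, which stabilises meiotic transcripts, stood at -2.88, Mei1, of meiotic recombination, at -5.29 and Stra8 at -5.93. PRC1.6 targets counted 13 higher and 9 lower of 25, over the list alone too (median 0.42, or -0.54 with spike-in scaling, camera adjusted p = 0.85). Early PGC genes counted 12 higher and 5 lower of 20 (median 0.98, camera adjusted p = 0.23) and male E13.5 genes 12 higher and 6 lower of 20 (median 1.06, camera adjusted p = 0.50), both the same over the list alone.

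Naive pluripotency genes were lower in 21 and higher in 7 of 31 cases, over the list alone too (median -1.64, camera adjusted p = 0.00026, but adjusted p = 0.50 with an estimated correlation), with Fgf4 at -9.59, Jam2 at -6.12 and Klf4 at -3.97. The 2-cell-like genes were lower in 20 and higher in 2 of 22 cases, over the list alone too (median -5.46, or -4.60 with bounds, camera adjusted p = 6.2e-08, but adjusted p = 0.50 with an estimated correlation and 0.24 on the 9-array filter). Glycolysis genes were lower in 21 and higher in 2 of 23 cases, over the list alone too (median -1.72, camera adjusted p = 6.2e-08, but adjusted p = 0.11 with an estimated correlation), with the glucose transporter gene Slc2a3 at -4.60 and Ldha at -4.62. MYC targets were higher in 42 and lower in 10 of 54 cases, over the list alone too (median 0.60, camera adjusted p = 0.0069, but adjusted p = 0.51 with an estimated correlation), and the median was -0.37 with spike-in scaling. Myc itself stood at -4.49.

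Formative epiblast genes were lower in 10 and higher in 3 of 18 cases (median -1.13, camera adjusted p = 0.0052, but adjusted p = 0.12 with an estimated correlation), p53 response genes in 15 and 1 of 23 (median -0.68, camera adjusted p = 0.00055, but adjusted p = 0.11 with an estimated correlation), and primitive endoderm genes in 14 and 3 of 20 (median -2.07, or -1.83 with bounds, camera adjusted p = 0.0022, but adjusted p = 0.51 with an estimated correlation). Cell cycle genes were lower in 23 and higher in 5 of 36 cases (median -0.54, camera adjusted p = 0.0024, but adjusted p = 0.51 with an estimated correlation), and immediate-early genes in 13 and 4 of 23 (median -1.28, camera adjusted p = 0.017, but adjusted p = 0.51 with an estimated correlation). Interferon response genes were lower in 12 and higher in 4 of 19 cases (median -1.31, or -0.9995 with bounds, camera adjusted p = 0.022, but adjusted p = 0.61 with an estimated correlation), a call lost without knockdown replicate 4 (median -0.97, adjusted p = 0.051). These 6 lists had the same counts over the list alone. Fibroblast genes counted 2 higher and 8 lower of 15 (median -0.55, camera adjusted p = 0.10), with Thy1 at -2.76 and Col3a1 at 3.33, the latter above background on 1 of 3 knockdown arrays. Markers of gonadal somatic cells counted 15 higher and 5 lower of 24 (15 and 6 adjusted over the list alone; median 1.74, or 1.39 with bounds, camera adjusted p = 0.21), and those of blood and endothelium 6 higher and 4 lower of 13 (median 0.46, or -0.50 with spike-in scaling and -0.46 with normexp on median signals, camera adjusted p = 0.94). Tie1 and Tek were at least 17.5-fold and 2.47-fold lower in PGCs.

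Changes against control were also compared between knockdown cells and PGCs. Of the germ cell genes, 40 were higher in both, 8 were higher in PGCs and did not pass in knockdown cells and 1 was higher in PGCs and lower in knockdown cells, and of the meiosis genes 26 were higher in both and 7 higher in knockdown cells but lower in PGCs. Of the 2-cell-like genes, 18 were higher in knockdown cells and lower in PGCs, and 7 fibroblast genes were lower in both. Over all genes, 2045 were higher in both, against 1610.5 for independent lists, and 2202 lower in both, against 1444. Opposite changes numbered 1001 higher in knockdown cells and lower in PGCs, against 1208.6, and 1376 the other way, against 1924.2. At 2-fold in both, 512 were higher in both, against 255.7 for independent lists, and 547 lower in both, against 199.9. Opposite changes at 2-fold numbered 339 higher in knockdown cells and lower in PGCs, above the 262.3 of independent lists, and 116 the other way, against 194.9. Pearson's r of the log2 changes across genes was 0.20, and 100 simulations of unchanged groups against the same controls gave 0.53 on average (0.20 to 0.78). Noise and shared controls alone set r in the simulations, so it is no yardstick for the observed r. The covariance was 0.25, against 0.03 on average in the simulations (highest 0.047), a difference of 0.22. No simulation called a gene in both comparisons, but unchanged groups cannot show what shared controls do to genes that changed. A division of the 3 control arrays would leave 1 of them for a comparison and was not run, so part of the excess of same-direction changes may come from shared controls.

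**Figure D3:**
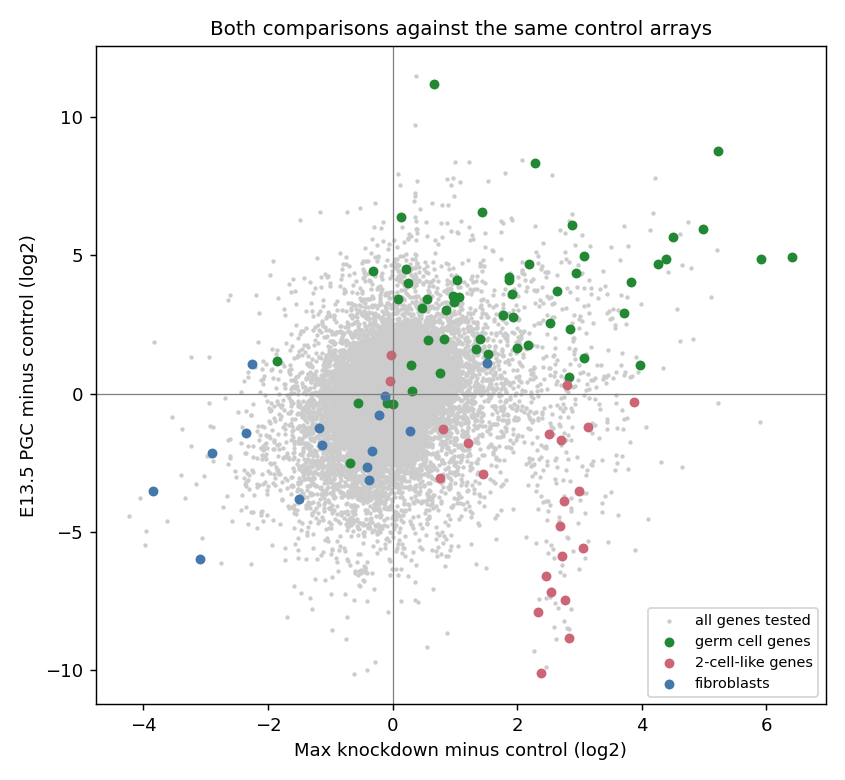
Log2 change in Max knockdown cells (x axis) against log2 difference of PGCs (y axis), both relative to control ES cells, 1 point per gene, with germ cell, 2-cell-like and fibroblast genes in colour. Germ cell genes lie mostly in the upper right, where 40 of 54 passed in both, and 2-cell-like genes in the lower right, where 18 of 22 passed in both.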

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

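Of the settings compared here, normexp on median signals was chosen after the data were seen, and its second version, without 14 spots, after its first result was seen. The planned normexp on mean signals was not run, because the scanner files used here hold no such column. Array signal over background bounds what any setting can show for dim genes.

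Spike-in scaling set the arrays by added control RNA. It called 1010 genes in Max knockdown against control, all 1010 at least 2-fold (70.6% higher, against 45.6%), 8787 in PGC against control (13.2% higher, against 57.1%) and 8324 in PGC against Max knockdown (12.1% higher, against 58.7%). The median of all genes moved to -0.07, -0.79 and -0.76 from -0.06, 0.18 and 0.21. Relative to the mean of the 9 arrays, the 75th percentile over the spike-ins was 0.55 and 0.71 in knockdown cells on slide 1 and -0.29 on slide 2. Control cells gave 0.74, 0.73 and -0.50. Without a slide block this difference entered the spread, so the fewer calls in Max knockdown against control do not show a shift between these groups. Genes higher in both comparisons against control numbered 194, against 2045. In PGC against control Max turned to -0.12, Sox4 to -0.30, Mdm2 to -0.46 and Ccnb2 to -0.61, and in PGC against Max knockdown Mdm2 turned to -0.16 and Ccnb2 to -0.38. The scaling moves every gene of an array alike, so these signs follow from the shift of the median and tell nothing about the genes themselves.

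Normexp on median signals called 887 genes in Max knockdown against control (65.1% higher), 718 at 2-fold (69.6% higher), 6119 and 4494 in PGC against control, 7217 and 5272 in PGC against Max knockdown, and 208 higher in both. The median of all genes moved to 0.27, 0.21 and -0.28. Ankrd1 turned to 0.12, Zbtb16 to 0.065, Cntd1 to 0.83, Wnt3 to 1.11, Pax3 to 0.50 and Sox9 to 0.63, and the naive pluripotency list had a median of 0.0032 with the test turned downward. On knockdown array 1, 11 spots had a background above their signal. The background mean that normexp fitted there was -1322.27, against 6.73 without such spots. Without them, 6816 genes passed in Max knockdown against control (49.8% higher), 1042 of them at 2-fold, against 8204 and 2282 in the main fit. The PGC comparisons had 5363 and 5190 genes at 2-fold, and 1831 genes were higher in both. In both normexp fits the offset of 50 draws log2 differences of dim genes toward 0. Its part in the lower counts at 2-fold was not tested. None of the genes named as turned above did so in this repeat, nor did the naive pluripotency list. For named genes 4 calls were lost, and for lists none.

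The filter on all 9 arrays left 1275 genes at 2-fold in Max knockdown against control and 5443 in PGC against Max knockdown. With 2-fold in both, 512 genes were higher in both. With an estimated correlation, germ cell genes kept their median of 1.65 but not the call (adjusted p = 0.0938). The mean of all probes of Sp110 gave 1.89 (adjusted p = 0.0007), where the probe used gave -0.05.

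With 1 array left out, Max knockdown against control called 6408 to 7067 genes, PGC against control 14539 to 15128 and PGC against Max knockdown 14819 to 15226, and the change of Max lay between -2.09 and -1.83. With replicate number as a block, 7366, 14803 and 13347 genes were called. This fit used only arrays whose number both groups share, and left 1, 2 and 1 residual degrees of freedom. The differences between replicates 1 and 2 correlated at 0.32 between control and knockdown, all on slide 1, and at -0.03 between PGC and knockdown. The differences between slides 2 and 1 correlated at 0.51 between control and knockdown. Deviations of control arrays from their mean correlated with those of PGC arrays at only -0.05 to 0.05. Control and knockdown arrays may thus share variation by number, but these values neither establish nor exclude a pairing.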

Other observations

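The tests of RNA carried over, of cross-hybridisation and of fibroblast RNA were chosen only after the result was seen.

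Germ cell genes rose in Max knockdown cells, with a median of 1.65, and the carry-over of RNA from PGCs between samples was weighed. Of 8 transcripts abundant in PGCs and not above background in control cells, the median rise over control was 0.358% of the difference between PGCs and control (quartiles 0.125% to 1.21%), and 4 of 8 rose, such as Asb9, against 43.5% for the 40 germ cell genes that rose in both, 11 of them above the PGC level. The 40 were chosen for rising in knockdown cells and the 8 were not, so part of this gap is built in. List members bright in PGCs that did not rise in knockdown cells, such as Stag3, are in neither set. Stag3 stood at 3.34 to 3.51 in PGCs and at -8.15 to -7.36 in knockdown cells. Carried-over PGC RNA would bring transcripts bright in PGCs alone to about the same share of the PGC level, and lift none above it. For the genes covered, the upper quartile of 1.21% and the 11 above the PGC level argue against carry-over as the whole cause. The within-slide median nearest to 0 was 1.42, and the lowest median under any scaling was 1.22 (normexp without the left-out spots), which argues against slide and scaling as the whole cause. Loss of MAX may have raised these genes, a hypothesis that no test here decides and that knockdown cells sorted without the Venus gate would test. The siRNA and the gate, which selects cells by a germ cell promoter, cannot be told apart here because they differ together.

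The 2-cell-like genes rose with a median of 2.62, and many of them have near-identical copies. The 8 members without such copies had a median of 1.13 and 6 of them rose, and without Sp110, whose kind was settled after its value was seen, 7 members had a median of 1.46 and 6 rose. Cross-hybridisation alone is argued against by these values, as is 1 culture by the lowest median with a knockdown array left out (2.40) and slide by the within-slide median nearest to 0 (2.49). A larger share of cells in the 2-cell-like state may underlie the rise, a hypothesis that was not tested and that counts of such cells in both cultures would test, and the Venus gate stays open.

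Fibroblast genes fell with a median of -1.13. The within-slide median nearest to 0 was -0.71, and that with a control array left out was -0.83, so these values argue against slide or a single control array as the whole cause. Normexp on median signals brought the median to -0.10 and ended the call (adjusted p = 0.19), and without the spots below their background it was -0.85 and the call with the fixed correlation stood (without normexp, adjusted p = 0.19 with an estimated correlation), 2 settings that replace both the signal column and the background step. Fibroblast RNA in control cells that the Venus gate removed would lower contractile and collagen genes alike, and contractile minus collagen members gave -2.58 (-3.47 and -0.89), but cells rich in contractile transcripts would give this too, so such cells and a loss within ES cells cannot be told apart. The collagens themselves went both ways, with Col1a2 at -2.36 and Col6a1 at 1.52, and both sets are small parts of the 15 members measured.

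Each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05, and 1 of them, the real one, reached its own count. In Max knockdown against control the real split called 8204 genes (2282 at 2-fold), in PGC against control 15418 (8178) and in PGC against Max knockdown 15584 (8187), and the highest of the other splits called 0 in each. Every other split mixes arrays of both groups, which puts their difference into the spread, so the 0 is no support for the real counts.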
